A study of Homo sapiens with 39 samples.

How the data were processed

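RNA was sequenced from 39 libraries of 4 human B cell lymphoma lines: DOHH2 and Toledo, which are lines of the germinal centre type, and OCILy10 and TMD8, which are lines of the activated B cell type. Per the labels, cells were treated for 6 h, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Each line had 3 libraries with DMSO, the vehicle, 3 with NEO2734, known as an inhibitor of the bromodomains of both the BET proteins and CBP/p300, and 3 with OTX015 (birabresib), a BET bromodomain inhibitor. OCILy10 had 3 more libraries with CB103, known as an inhibitor of the Notch transcription complex. The labels gave no doses, so the compounds were not compared at known matched doses. Part of the label text shared by all samples named other compounds and a longer treatment than each sample's own label, and the sample's own label was used. The labels did not say whether the 3 libraries of a group came from separate cultures, so every p-value measures the spread between libraries only.

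The authors deposited 2 tables of counts per gene for the same 39 libraries and 15808 versioned Ensembl gene IDs. Both hold whole numbers whose totals differ between libraries, although the name of 1 calls its values normalised. A cell by cell comparison found 38 columns equal and 1 different, that of OCILy10 CB103 replicate 1, so the table named as raw counts was used and the other column served as an alternative. The submitters' processing notes name STAR, edgeR and the build hg38, and their versions are not given in the sources used here. The program that counted reads, the annotation used for counting and the strandedness of the libraries are also not given in the sources used here. Values of genes that overlap another gene on the opposite strand, such as the antisense gene SLC16A1-AS1, may therefore hold reads of both. All 39 column names matched a sample title, with 0 left unmapped. Symbols were attached by gene ID for 14179 genes, and 1629 IDs had none. Coordinates were taken from GENCODE 29 on GRCh38 (hg38).

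Library totals ranged from 1000281 to 11668542 counts. They fell into 24 libraries of at most 3420458 counts (median 1801501.5) and 15 of at least 6670250 (median 8368887), called shallow and deep below. The deep set held 1 library of each of the 13 groups and 1 more each of OCILy10 DMSO and OCILy10 NEO2734. Levels are counts scaled to library size and by TMM factors (CPM) and are given as mean ± SD with n = 3. Where a group held 0 counts, 3 counts over the group were taken as its upper limit, and for groups with 1 to 3 counts the ratio has a 95% exact counting interval. Intervals and floors cover counting error only.

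The fit was made in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr by group, a coefficient for each of the 13 groups and 26 residual degrees of freedom), and 12814 genes were tested. Contrasts were each compound against DMSO and NEO2734 against OTX015 within each line, CB103 against DMSO in OCILy10, the plain mean over the 4 lines, and an F-test with 3 numerator degrees of freedom for a difference between the lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and ± after a log2 fold change is its SE. The averaged contrast speaks of these 4 lines only. On simulated counts with the groups' own depths and spread, the averaged NEO2734 contrast found 94% of genes raised 4-fold and 54% of genes raised 2-fold, and 92% of genes lowered 4-fold and 72% of genes lowered 2-fold, with 14 false calls among 170. The same test within DOHH2 found 56% of genes raised 4-fold and 16% of genes raised 2-fold, and 62% of genes lowered 4-fold and 2% of genes lowered 2-fold, with 4 false calls among 72.

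All comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, except where said otherwise. The rule named, for each averaged contrast, up to 10 rises and 10 falls of the largest size among genes called for the mean and in at least 3 lines with the same sign, called in no line with the other sign, and with a mean of at least 5 CPM in a group. Within a line it named up to 3 rises and 3 falls of called genes whose 3 and 3 libraries did not overlap. For CB103, with none called, it named the 5 lowest p as not passing. For each F-test it named the 5 lowest p. MYC, HEXIM1, SERPINI1, BRD2, BRD3, CREBBP, EP300, BCL2, BCL6, IRF4 and CDKN1A were read everywhere, and NOTCH1, NOTCH2, RBPJ, HES1, HES4, NRARP and DTX1 with CB103. The 10% given beside shares of genes with groups apart holds for exchangeable libraries. Depth differs within groups and numbers pair libraries in some contrasts, so the share without any change may lie lower, and it is no exact baseline. Up to 4 members stand for a list. Features without a symbol and copies or pseudogenes were counted but not named.

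The 27 lists were written from textbook knowledge: BET inhibition markers, histone, MYC target, NF-kB target, B cell receptor pathway, B cell transcription factor, germinal centre B cell-like, activated B cell-like, cell cycle, pro-survival BCL2 family, pro-death BCL2 family and death receptor, interferon-stimulated, MHC class II, Notch pathway, p53 target, cholesterol synthesis, ER stress, heat shock, immediate early, autophagy and lysosome, glycolysis, BET and CBP/p300 and elongation factor, cytosolic ribosomal protein, mitochondrially encoded, T cell marker, monocyte marker and plasma cell genes. They were tested with camera (limma 3.58.1) at the preset correlation of 0.01 between genes, adjusted over the 27 lists of a contrast, and again with an estimated correlation and with fry. Some genes stand in more than 1 list.

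Alternatives fixed in advance were DESeq2 size factors, library totals or upper quartile scaling, no filter and a stricter filter, DESeq2 1.42.0 (Wald test), limma-voom, a block for the replicate number, a fit of 1 line's libraries alone, and leaving out each library in turn. A left-out library leaves 2 in its group, which are assumed to vary like the other groups. Further alternatives were chosen after the data were seen: without 3 libraries that held genes of another line, a depth term within each line, both together with each of 3 scalings, the shallow or the deep libraries alone, and the second table's column for OCILy10 CB103 replicate 1. In the deep set most groups have a single library, whose spread is taken from OCILy10. Replicate numbers were taken to pair the libraries of 2 groups where, for each of the 3 numbers, the libraries' deviations from their group means correlated above 0.1 across genes. This held for the 3 contrasts in DOHH2, the 3 in TMD8 and NEO2734 against DMSO in OCILy10. In these groups deep libraries carry the same numbers and the deviations kept depth, so depth alone could give such correlations. In DOHH2, 1 of 3 NEO2734 libraries correlated best with the DMSO library of its own number, and in OCILy10 3 of 3. Numbers said to pair are those above this threshold, which does not show paired cultures. The threshold was not met in Toledo, where the deep NEO2734 library is replicate 3 while replicate 1 is deep in the other 12 groups, so the Toledo numbers may not follow the same order. Blocked values for Toledo, for the averages and between lines use these numbers all the same. The call counts with the block, the depth term and without the 3 libraries had been seen before this check, and the decision followed the fixed threshold alone. Blocked counts stand beside those of the lines where numbers pair if they differ by over 1.5 times. Other splits of the libraries numbered 10 within a line, and 50 were drawn for each averaged contrast because each needs its own fit. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.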

Results

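The data comprise 39 RNA-seq libraries of 4 lymphoma cell lines in 13 groups of 3: DMSO, NEO2734 and OTX015 in DOHH2, OCILy10, TMD8 and Toledo, and CB103 in OCILy10. Library totals ranged from 1000281 to 11668542 counts, with 15 deep and 24 shallow libraries. Between 13017 and 15167 genes had a count, and mitochondrially encoded genes took 5.31 to 12.7% of the counts. Principal components were taken after each line's mean was subtracted, so differences between the lines are not in them. The first held 47.9% of the remaining variance and parted the deep from the shallow libraries, and the second held 10.4%.

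Genes private to 1 line numbered 18 for DOHH2, 8 for OCILy10, 11 for TMD8 and 13 for Toledo. They had over 10 CPM in each library of the line and under 1 CPM at the 90th percentile of the other lines' libraries. The 3 libraries named below were left out of this choice, so low shares in the other 36 follow in part from the rule. In 36 libraries the genes of each other line stood at a median of at most 2.30% of their level in that line. Toledo DMSO replicate 2 held the OCILy10 genes at 70.4% and its own at 41.5%. OCILy10 CB103 replicate 2 held the Toledo genes at 27.1% and its own at 75.1%. DOHH2 NEO2734 replicate 3 held the OCILy10 genes at 12% and its own at 70.5%. In the other 36 libraries a line's own genes stood at 63.3 to 156% of their level. All 3 libraries were kept in the fit.

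**Figure D1:**
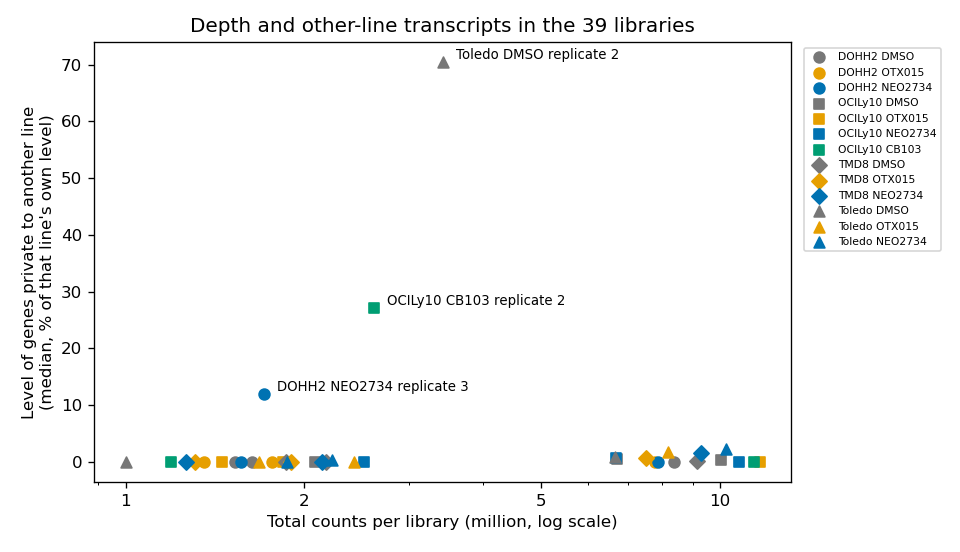
Total counts per library (log scale) against the median level of the genes private to another line (percent of their level in that line) for the 39 libraries, with shape by line and colour by treatment. The 3 labelled libraries lie at 12, 27.1 and 70.4%, and the other 36 at 2.30% or less.

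The first comparison asked which genes responded to NEO2734 within 6 h across these lymphoma lines, as the mean of the 4 within-line changes. HEXIM1 (ENSG00000186834.3, chromosome 17, 45148502 to 45152101), whose product holds the elongation factor P-TEFb inactive, rose 4.29-fold (log2 2.10 ± 0.24, adjusted p = 2.67e-07). Its level went from 44.7 ± 11.1 to 176 ± 57.8 CPM in DOHH2 and from 52.0 ± 19.7 to 292 ± 163 CPM in Toledo, and in each of the 4 lines all 3 compound libraries lay above all 3 DMSO libraries. MYC (ENSG00000136997.13, chromosome 8, 127735434 to 127741434), a transcription factor that drives growth, fell to 0.384 of its DMSO level (log2 -1.38 ± 0.22, adjusted p = 4.39e-05), and its groups did not overlap in DOHH2 and TMD8. ZSWIM6 (ENSG00000130449.5, chromosome 5, 61332273 to 61546170), a zinc finger gene, rose 4.36-fold, and LAT2 (ENSG00000086730.15, chromosome 7, 74199652 to 74229834), an adaptor in B cell receptor signalling, fell to 0.264 of its DMSO level. Both had an adjusted p of 1.1e-11 and groups that did not overlap in any of the 4 lines.

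Under the naming rule, which 74 genes met, the largest rise was that of DHRS2 (ENSG00000100867.13, chromosome 14, 23630115 to 23645639), a short-chain dehydrogenase, at 10.5-fold (log2 3.40 ± 0.42, adjusted p = 1.33e-06). Its level in OCILy10 went from 5.59 ± 2.52 to 100.5 ± 37.2 CPM. The RNA-binding protein gene KHDRBS3 (3.10 ± 0.35, with 0 counts in DOHH2 DMSO, so that its mean is no bound), the cell surface hyaluronidase gene CEMIP2 (2.87 ± 0.30), the zinc finger gene ZCCHC24 (2.80 ± 0.37) and PPP1R13B, which encodes a partner of p53 (2.12 ± 0.21), also rose. So did the magnesium transporter gene CNNM4 (2.003 ± 0.20), USP53 of the ubiquitin protease family (1.90 ± 0.21) and PGM2L1, an enzyme of sugar phosphates (1.86 ± 0.26). Their adjusted p ranged from 2.84e-08 (CNNM4) to 5.11e-06 (PGM2L1), and of these 8 genes 6 had groups apart in all 4 lines. DHRS2 and PGM2L1 had them apart in 3 lines. The largest falls under the rule included the Fc receptor-like gene FCRL2 (-2.59 ± 0.29), the proton channel gene HVCN1 (-2.40 ± 0.30), the corepressor gene CBFA2T3 (-2.08 ± 0.23), the cytokine gene IL16 (-2.04 ± 0.22) and the lymphocyte adaptor gene SASH3 (-1.87 ± 0.15). APOL6, an apolipoprotein L gene (-2.54 ± 0.27), GRAMD1B, a sterol carrier (-2.46 ± 0.25), JADE2, of a histone acetyltransferase complex (-2.32 ± 0.25), and DDN (-2.23 ± 0.27) fell too. Adjusted p for these 9 genes ranged from 7.13e-10 (SASH3) to 1.27e-06 (HVCN1), and the groups were apart in all 4 lines, or in 3 for HVCN1.

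Of the genes read in every comparison, SERPINI1, a serpin gene known to rise with BET inhibitors, rose (2.57 ± 0.52, adjusted p = 0.000533), as did BRD2, a BET protein gene (0.55 ± 0.08, adjusted p = 1.8e-05), while the B cell transcription factor gene IRF4 fell (-0.73 ± 0.19, adjusted p = 0.00654). BRD2 (adjusted p = 0.0686) and IRF4 (0.072) did not pass in the deep libraries alone. The BET gene BRD3 (0.33 ± 0.18), the acetyltransferase genes CREBBP (0.09 ± 0.10) and EP300 (0.20 ± 0.12), and BCL2 (-0.34 ± 0.24), BCL6 (1.07 ± 0.65, with an empty group in 1 line) and CDKN1A (0.09 ± 0.23) did not pass, with adjusted p from 0.215 to 0.894. Without Toledo DMSO replicate 2, BCL6 (adjusted p = 0.0255) and CDKN1A (0.0463) passed.

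Of the 12814 genes tested, 2630 were called, 1191 higher and 1439 lower, and 301 and 583 of these changed at least 2-fold. At an unadjusted p under 0.05 there were 3930. The balance of higher and lower genes is that of all libraries. Toledo DMSO replicate 2, the library with OCILy10 genes, lies on the DMSO side. Without the 3 libraries that held another line's genes 2141 genes were called. The shallow libraries alone gave 1813 genes and the deep ones alone 727. Across 12266 genes the changes within the deep and the shallow libraries correlated at r = 0.677, and 79.0% had the same sign, where genes are not independent replicates. In all 4 lines with the same sign, 27 genes were called, 15 higher, among them CEMIP2, CNNM4, ZSWIM6, PPP1R13B and the mRNA export factor gene NXF1, and 12 lower, among them LAT2, IL16, CBFA2T3, SASH3 and the zinc finger gene ZHX2. This count was 16 without the 3 libraries that held another line's genes, 1 in the shallow libraries alone, 68 with DESeq2 and 114 with the replicate block.

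Histone genes rose as a group with NEO2734: 11 of 17 tested rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 change of 2.01 (adjusted p = 1.51e-12). H2BC21 rose by 3.13 ± 0.42 and H2BC5 by 2.71 ± 0.38. Of 17 markers of BET inhibition, 9 rose and 5 fell (10 and 5 adjusted over the list alone), among them HEXIM1, SERPINI1 and, downward, the chemokine receptor gene CCR1 (-3.47 ± 0.51), which had an empty group in 1 line (median 1.43, adjusted p = 0.00209). Of 33 autophagy and lysosome genes, 13 rose and 2 fell (13 and 3 adjusted over the list alone), such as the sialidase gene NEU1 (1.53 ± 0.20) and, lower, the protease gene CTSS (-0.71 ± 0.12), with a median of 0.28 (adjusted p = 0.000514). Immediate early genes (8 of 25 rose and 1 fell, 8 and 3 adjusted over the list alone, median 0.41, adjusted p = 0.0378 and 0.324 with an estimated correlation) included ZFP36, a factor of mRNA decay, at 1.04 ± 0.19, and the transcription factor gene FOSB at 1.67 ± 0.36. Of 28 BET, CBP/p300 and elongation factor genes, 8 rose, HEXIM1 and BRD2 among them, and 1 fell, with the same counts adjusted over the list alone (median 0.11, adjusted p = 0.00763 and 0.0759 with an estimated correlation). In the deep libraries alone ZFP36 (adjusted p = 0.0545) and FOSB (0.189) did not pass.

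Interferon-stimulated genes fell: 27 of 34 fell and 1 rose, also adjusted over the list alone, with a median of -1.90 (adjusted p = 8.72e-23). The antiviral gene OAS2 changed by -2.88 ± 0.34 and the restriction factor gene TRIM22 by -1.74 ± 0.20. MYC target genes fell in 34 of 58 cases and rose in 0 (41 and 0 adjusted over the list alone, median -0.60, adjusted p = 7.77e-16), with the methyltransferase gene PRMT3 at -0.95 ± 0.13 and the RNA polymerase I subunit gene POLR1B at -0.70 ± 0.10. B cell transcription factor genes fell in 17 of 28 cases and rose in 0 (18 and 0 adjusted over the list alone, median -0.88, adjusted p = 7.93e-12), among them PAX5, which sets B cell identity (-1.54 ± 0.12, adjusted p = 2.22e-10), and IKZF1 (-1.69 ± 0.23). B cell receptor pathway genes fell in 17 of 30 cases and rose in 0 (18 and 0 adjusted over the list alone, median -0.68, or -0.70 with genes of an empty group at their bound, adjusted p = 3.12e-07), such as MS4A1, which encodes CD20 (-1.57 ± 0.25), and CD72 (-1.65 ± 0.29). Plasma cell genes fell in 6 of 15 cases and rose in 0 (8 and 0 adjusted over the list alone, median -0.78, or -0.73 at the bound, adjusted p = 0.000514), such as the receptor gene TNFRSF17 (-2.99 ± 0.59).

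Activated B cell-like genes fell in 12 of 20 cases and rose in 0, also adjusted over the list alone (median -0.64, adjusted p = 1.1e-06 and 0.142 with an estimated correlation), with IL16 and the transcription factor gene ETV6 (-0.995 ± 0.16). MHC class II genes fell in 5 of 16 cases and rose in 0, also adjusted over the list alone (median -0.59, adjusted p = 0.00209 and 0.0759 with an estimated correlation), such as their activator gene CIITA (-1.76 ± 0.23) and RFX5 (-0.68 ± 0.11). NF-kB target genes fell in 11 of 35 cases and rose in 1 (16 and 1 adjusted over the list alone, median -0.53, adjusted p = 0.00533 and 0.596 with an estimated correlation), among them the chemokine gene CXCL10 (-3.94 ± 0.61) and the costimulatory gene CD80 (-2.08 ± 0.32). Toledo DMSO replicate 2, with the OCILy10 genes at 70.4% of their level, lies on the DMSO side of these lists, and all 13 lists called stayed called without the 3 libraries that held another line's genes. Of 50 drawn splits within lines, 8 called 13 or more lists, the real one included. With an estimated correlation 8 of the 13 calls held.

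The remaining lists were not called with NEO2734. Adjusted p was 0.0773 for the germinal centre B cell-like genes (1 rose and 6 fell of 16, 2 and 6 adjusted over the list alone). It was 0.111 for the p53 target genes (6 rose and 1 fell of 23, also adjusted over the list alone), with SESN1 at 0.91 ± 0.14 and the nuclease gene AEN at -0.96 ± 0.14, and 0.111 for the heat shock genes (1 and 3 of 14, 1 and 4 adjusted over the list alone). It was 0.375 for the pro-survival BCL2 family (1 and 2 of 10, 1 and 3 adjusted over the list alone) and for the pro-death list (1 and 3 of 17, 1 and 4 adjusted over the list alone), with APAF1, an activator of caspases, at 0.66 ± 0.13. The glycolysis (2 and 2 of 23) and Notch pathway (3 and 4 of 19) lists had an adjusted p of 0.643, with the same counts adjusted over the list alone, and TXNIP, an inhibitor of glucose uptake, rose by 1.30 ± 0.16. For cholesterol synthesis genes 1 rose and 2 fell of 23 (adjusted p = 0.726), and for ER stress genes 1 rose and 0 fell of 23 (0.755), with the same counts adjusted over the list alone and, for the latter, a median of -0.02 beside an upward test. Of 38 cell cycle genes 0 rose and 1 fell (0 and 0 adjusted over the list alone, adjusted p = 0.985, median 0.01 beside a downward test). None of 74 ribosomal protein genes (adjusted p = 0.631), 15 mitochondrially encoded genes (0.375), 4 T cell markers (0.985, median -1.20 beside an upward test) or 3 monocyte markers (0.932) passed on its own, with the same counts adjusted over the list alone.

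**Figure D2:**
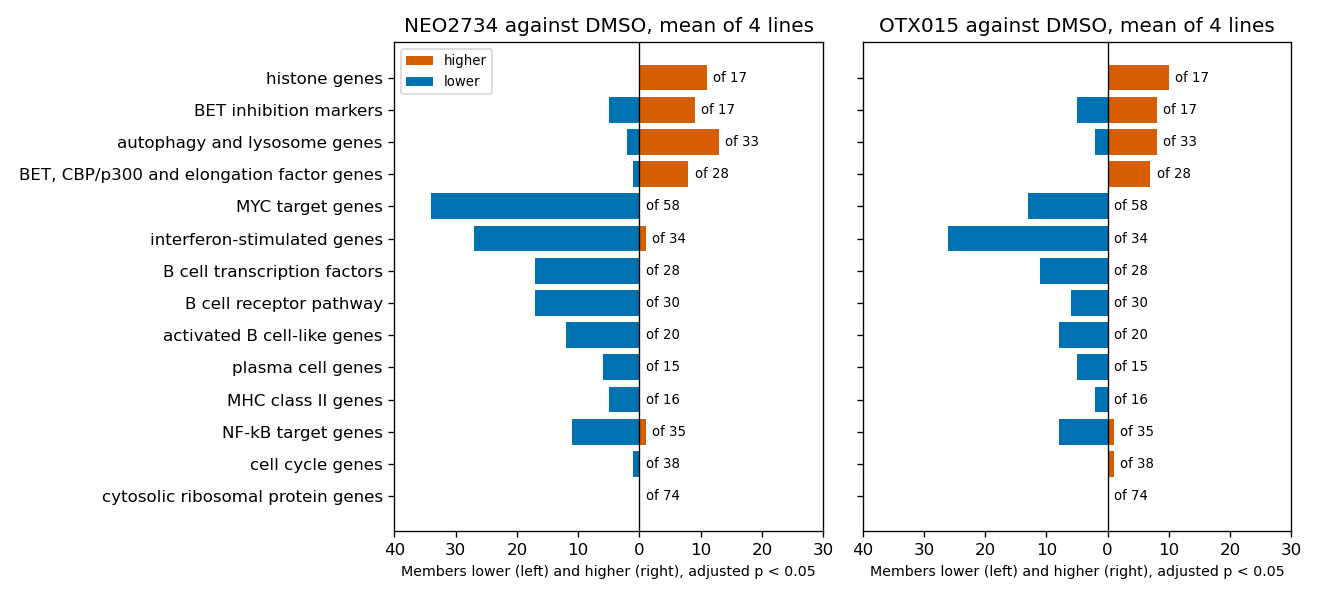
Number of members called lower (bars to the left) and higher (bars to the right) against DMSO at an adjusted p under 0.05 for 14 gene lists, as the mean of the 4 lines. There is a panel for NEO2734 and a panel for OTX015, with the size of each list to the right of its bars. Interferon-stimulated genes have the longest bar in proportion, with 27 and 26 of 34 lower, and histone genes lie on the other side with 11 and 10 of 17 higher.

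Within DOHH2 the question was what NEO2734 changed in this line alone, with 3 libraries against 3. WNT10A, a secreted Wnt ligand gene, fell from 15.7 ± 9.12 to 1.04 ± 0.439 CPM (log2 -3.78 ± 0.77, adjusted p = 0.00587). Its relative WNT10B had 2 counts against 90 (ratio 0.0227, 95% interval 0.0027 to 0.0842, adjusted p = 0.00601). PITPNM2, a lipid transfer gene, fell by 4.15 ± 0.86 (adjusted p = 0.00675). PEG10, an imprinted gene, rose from 36.6 ± 12.2 to 844 ± 564 CPM (4.51 ± 0.98, adjusted p = 0.00982), and IQCN rose by 4.43 ± 1.26 (adjusted p = 0.0496). GTSF1, known from germ cells, had 31 counts against 1 (ratio 31.6, 95% interval 5.27 to 1288, adjusted p = 0.0171). GTSF1 reached 15.4 CPM in NEO2734 replicate 3, the library with OCILy10 genes, and stood at 157 CPM in OCILy10 DMSO. HEXIM1 rose by 1.98 ± 0.48 (adjusted p = 0.0183) and MYC fell by 1.63 ± 0.45 (adjusted p = 0.042), from 265 ± 54.7 to 85.5 ± 28.8 CPM. Of 58 MYC target genes, 13 fell and 0 rose (median -0.86, adjusted p = 2.6e-24 and 0.0031 with an estimated correlation), and 8 of 17 histone genes rose.

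In DOHH2 with NEO2734, 372 genes were called, 183 higher and 189 lower (141 and 122 at least 2-fold), with 1929 at an unadjusted p under 0.05. Higher and lower genes numbered 261 and 187 with library totals, 233 and 169 with upper quartile scaling and 142 and 225 with limma-voom, and a fit of the DOHH2 libraries alone called 17 and 51. The groups did not overlap for 356 of the 372 and for 18.4% of all genes, where exchangeable libraries would give 10%. With the replicate number as a block 951 genes were called, the shallow libraries alone gave 193 and the deep ones 0. Leaving out DMSO replicate 2 or 3 gave 148 or 119 genes and leaving out NEO2734 replicate 2 or 3 gave 169 or 147. The GTSF1 call was lost without NEO2734 replicate 3 (adjusted p = 0.952) or DMSO replicate 1, 2 or 3 (0.121, 0.0592, 0.0653), and that of PEG10 without DMSO replicate 2 or 3 (0.067, 0.0686). IQCN was lost without any 1 of the 6 libraries (0.0548 to 0.196). MYC was lost without DMSO replicate 1, 2 or 3 (0.109, 0.123, 0.0767) or NEO2734 replicate 2 or 3 (0.163, 0.20), and HEXIM1 without the same 5 (0.0565 to 0.0881).

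Within OCILy10, NEO2734 raised DHRS2 (4.14 ± 0.83, adjusted p = 0.00995), the microtubule protein gene MAP1A (3.45 ± 0.68, adjusted p = 0.00935) and the testis gene TEX14 (2.81 ± 0.63, adjusted p = 0.021). The glycosyltransferase gene MGAT3 fell by 3.28 ± 0.72 (adjusted p = 0.0183), GRAMD1B by 2.75 ± 0.50, and CBFA2T3 fell by 2.59 ± 0.47 (both adjusted p = 0.00439). HEXIM1 was at 157 ± 59.9 against 50.4 ± 20.5 CPM without passing (1.65 ± 0.47, adjusted p = 0.0776), and it passed with the replicate number as a block (0.0039). MYC was at -0.53 ± 0.44 (adjusted p = 0.817). Of 28 B cell transcription factor genes 3 fell (median -0.42, adjusted p = 3.9e-07 and 0.033 with an estimated correlation), and of the interferon-stimulated genes 0 passed. In all 130 genes were called, 84 higher and 46 lower (64 and 35 at least 2-fold), with 1411 at an unadjusted p under 0.05. All 130 had groups that did not overlap, as had 19.95% of all genes, where exchangeable libraries would give 10%. The excess of higher genes was absent with the block (648 genes, 320 higher and 328 lower) and limma-voom (206 and 240), and small without the 3 libraries that held another line's genes (111 and 103). A fit of the OCILy10 libraries alone called 59 higher and 90 lower. The deep libraries alone gave 120 genes and the shallow ones 2. Each left-out library lowered the count: to 41, 58 and 31 without DMSO replicates 1, 2 and 3, and to 64, 44 and 31 without NEO2734 replicates 1, 2 and 3. DHRS2 was lost without DMSO replicate 1 or 3 (0.0819, 0.0718). MAP1A was lost without DMSO replicate 1 or 2 or NEO2734 replicate 3 (0.089, 0.0508, 0.0777). TEX14 was lost without any but NEO2734 replicate 1 (0.0717 to 0.108) and MGAT3 without any but DMSO replicate 1 (0.0551 to 0.111).

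Within TMD8, NEO2734 lowered interferon-stimulated genes: 19 of 34 fell and 0 rose (median -2.95, adjusted p = 1.3e-49 and 0.0017 with an estimated correlation). IFIT1, whose product binds viral RNA, fell from 194 ± 93.9 to 5.79 ± 5.83 CPM (log2 -5.17 ± 1.05, adjusted p = 0.00476), OASL fell by 6.00 ± 1.17 (adjusted p = 0.00359). IFI44 had 0 counts against 88, at least 28.9-fold lower (adjusted p = 0.00563). MYC fell from 210 ± 138 to 20.9 ± 2.67 CPM (log2 -3.31 ± 0.49, adjusted p = 0.000201), and HEXIM1 rose by 2.26 ± 0.48 (adjusted p = 0.00717). The myosin gene MYH15 (4.30 ± 1.16, adjusted p = 0.0449), DHRS2 (4.25 ± 0.87, adjusted p = 0.00557) and EFR3B, a membrane protein gene (4.11 ± 0.99, adjusted p = 0.0216), rose. In all 278 genes were called, 93 higher and 185 lower (66 and 172 at least 2-fold), with 1534 at an unadjusted p under 0.05. Library totals as the scaling gave 302 genes, 51.0% of them higher, against 33.5% with TMM. The groups did not overlap for 274 of the 278 and for 17.9% of all genes, where exchangeable libraries would give 10%. The block gave 751 genes and brought SERPINI1 (0.0436) and BCL2 (0.0199) past the threshold, the shallow libraries alone gave 92 and the deep ones 0. The count was 181, 162 and 103 without DMSO replicates 1, 2 and 3, and 136, 106 and 178 without NEO2734 replicates 1, 2 and 3. MYH15 was lost without any library but NEO2734 replicate 3 (0.0913 to 0.222). EFR3B was lost without DMSO replicate 1, 2 or 3 or NEO2734 replicate 2 (0.0572 to 0.128). DHRS2 was lost without DMSO replicate 3 (0.0538), IFI44 without NEO2734 replicate 1 (0.0791) and IFIT1 without NEO2734 replicate 2 (0.0535).

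Within Toledo, NEO2734 raised CAPN5, a calpain protease gene, to 81 counts against 1 (ratio 65.2, 95% interval 11.4 to 2608, adjusted p = 0.00473), and TUFT1 to 77 counts against 2 (ratio 31, 95% interval 8.30 to 261, adjusted p = 0.00914). It raised the histone gene H2BC5 by 3.76 ± 0.81 (adjusted p = 0.00717). HEXIM1 rose by 2.51 ± 0.48 (adjusted p = 0.00325), while MYC was at 179 ± 34.5 against 187 ± 37.4 CPM (log2 -0.06 ± 0.44, adjusted p = 0.996). The lowest values belonged to MYOCD, a muscle coactivator gene with 1 count against 427 (ratio 0.00189, 95% interval 4.76e-05 to 0.0106, adjusted p = 0.00473), the interferon-induced gene GBP1 (-6.73 ± 1.24, adjusted p = 0.00275) and the adhesion gene CHL1 (-6.59 ± 1.26, adjusted p = 0.00325). Their DMSO levels were carried by replicate 2, the library with OCILy10 genes, at 115, 85.2 and 91.8 CPM against at most 4.1 CPM in the other DMSO libraries. Without that library MYOCD, GBP1 and CHL1 were not called (adjusted p = 0.522, 0.153 and 0.251), nor were TUFT1 (0.0697) and H2BC5 (0.0709). In all 701 genes were called, 163 higher and 538 lower (103 and 515 at least 2-fold), with 2180 at an unadjusted p under 0.05. A fit of the Toledo libraries alone called 0 genes (adjusted p = 0.170 for HEXIM1 and 0.134 for CAPN5), and limma-voom called 170 higher and 137 lower. Without DMSO replicate 2 the count was 90, without DMSO replicate 1 it was 1136, and without NEO2734 replicates 1, 2 and 3 it was 171, 168 and 405. Without the 3 libraries that held another line's genes it was 82, in the shallow libraries alone 739 and in the deep ones 0. The groups did not overlap for 396 of the 701 and for 13.1% of all genes, where exchangeable libraries would give 10%. In this line 14 of 34 interferon-stimulated, 11 of 20 activated B cell-like and 8 of 35 NF-kB target genes fell, all on the side of that DMSO library.

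Whether the lines differed in their response to NEO2734 was tested gene by gene, and 2 genes passed, PAX5 and ALKBH5 (both adjusted p = 0.0395), with 783 at an unadjusted p under 0.05. PAX5 (ENSG00000196092.11, chromosome 9, 36833275 to 37034185) fell in DOHH2 (192 ± 44.7 to 68.9 ± 11.4 CPM, adjusted p = 0.00071), OCILy10 (311 ± 72 to 74.1 ± 2.59 CPM, 9.1e-06) and TMD8 (651.5 ± 127 to 128 ± 28.3 CPM, 1.4e-06), and stood at 256 ± 34.0 against 312 ± 25.7 CPM in Toledo (0.66). ALKBH5 (ENSG00000091542.8, chromosome 17, 18183078 to 18209954), an RNA demethylase gene, rose in OCILy10 (58.1 ± 14.5 to 395 ± 144 CPM, 7.5e-06) and TMD8 (63.5 ± 19.4 to 160 ± 36.5 CPM, 0.011) and did not pass in DOHH2 (log2 0.31) or Toledo (0.53). For MYC (adjusted p = 0.276), IFIT3 and MSL3, the other lowest p, the lines were not shown to differ, and HEXIM1 had an adjusted p of 1. Over the alternatives the F-test of PAX5 ranged from an adjusted p of 0.00095 to 1 and that of ALKBH5 from 3.3e-06 to 1. With the shallow libraries alone both had 0.52 and with the deep ones 1.

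**Figure D3:**
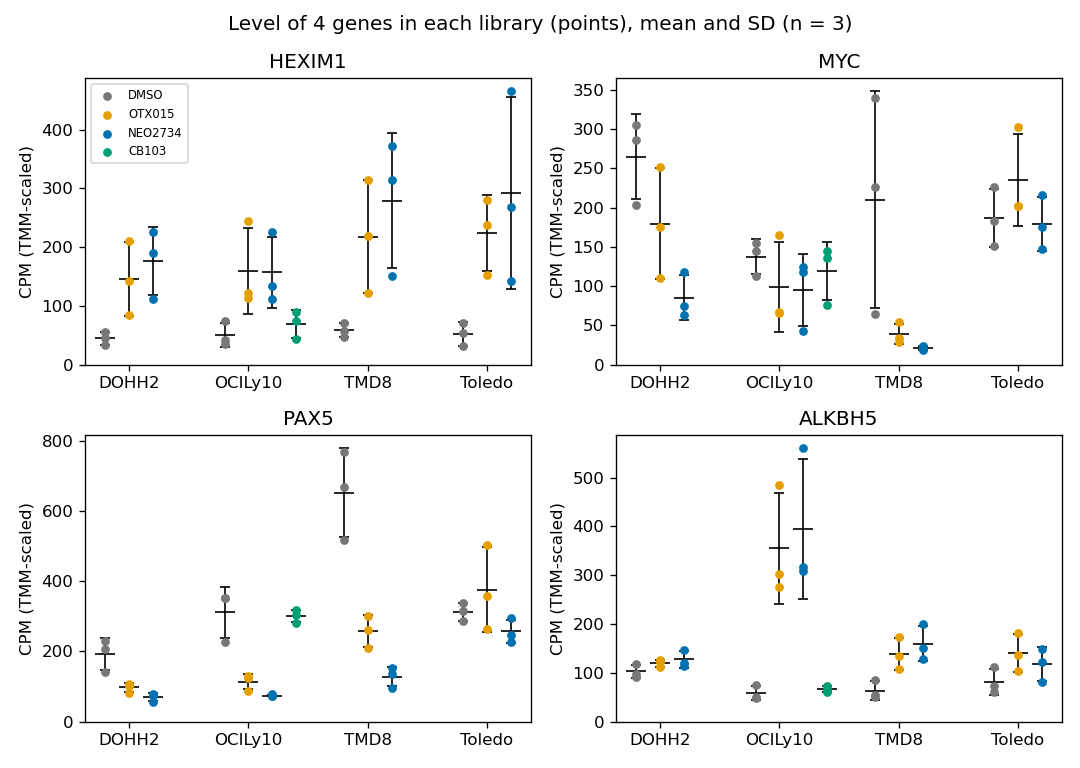
Level of HEXIM1, MYC, PAX5 and ALKBH5 (TMM-scaled CPM) by line and treatment, with a point per library and bars for the mean and SD of 3 libraries. HEXIM1 with NEO2734 lies above DMSO in all 4 lines, while PAX5 in Toledo stands at 256 ± 34.0 CPM with NEO2734 and 312 ± 25.7 with DMSO.

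The same question for OTX015, a BET inhibitor, gave a response averaged over the 4 lines in which HEXIM1 rose (1.85 ± 0.24, adjusted p = 8.12e-06), with groups apart in all 4 lines. Its level went from 58.2 ± 11.9 to 218 ± 96.3 CPM in TMD8. ZSWIM6 rose 3.24-fold (1.70 ± 0.14, adjusted p = 3.6e-09), and the largest rises under the rule were completed by NXF1 (1.05 ± 0.10) and HYCC1, a gene of lipid kinase recruitment (0.80 ± 0.07). LAT2 fell (-1.53 ± 0.13, adjusted p = 3.6e-09), from 278 ± 52.4 to 104 ± 2.87 CPM in DOHH2, as did the fatty acid enzyme gene ACSL5 (-1.05 ± 0.11), TTC27 (-1.03 ± 0.10) and the chromatin reader gene ZMYND8 (-0.89 ± 0.11). These 7 were all the genes that met the rule, with adjusted p of at most 3.9e-06 and groups apart in all 4 lines. MYC fell on this average (-0.77 ± 0.22, adjusted p = 0.0196), with groups apart in TMD8, and was not called without TMD8 DMSO replicate 3 (0.0576). Within lines, as given below, MYC was called in TMD8 and did not pass in OCILy10, so the average does not show a fall in each line. BRD2 rose (0.55 ± 0.08, adjusted p = 5.98e-05) and IRF4 fell (-0.63 ± 0.19, adjusted p = 0.0316), although IRF4 was not called (0.0522 to 0.0885) without any 1 of DOHH2 DMSO 3, DOHH2 OTX015 1, OCILy10 OTX015 2, TMD8 DMSO 1, TMD8 DMSO 3, TMD8 OTX015 2, TMD8 OTX015 3, Toledo DMSO 2, Toledo OTX015 2 or Toledo OTX015 3. SERPINI1 (1.48 ± 0.54, adjusted p = 0.0726) passed without Toledo DMSO replicate 2 (0.00627). BRD3 (0.46 ± 0.18), CREBBP (0.11 ± 0.10), EP300 (0.32 ± 0.12), BCL2 (0.15 ± 0.24), BCL6 (0.02, with an empty group in 1 line) and CDKN1A (-0.27 ± 0.23) did not pass (adjusted p = 0.0746 to 0.902), and EP300 passed without Toledo DMSO replicate 2 (0.0277) or DOHH2 OTX015 replicate 1 (0.0457).

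In this average 1484 genes were called, 708 higher and 776 lower (147 and 350 at least 2-fold), with 3038 at an unadjusted p under 0.05. This balance of higher and lower genes is that of all libraries. Toledo DMSO replicate 2, the library with OCILy10 genes, lies on the DMSO side, and 1273 genes were called without it. The shallow libraries alone gave 951 and the deep ones 62, where MYC (adjusted p = 0.142), HYCC1 (0.0697), ACSL5 (0.105) and TTC27 (0.0755) were not called. The changes within the deep and the shallow libraries correlated across genes at r = 0.533, with the same sign for 70.0%. In all 4 lines with the same sign 2 genes were called, HYCC1 and LAT2. This count was 1 without the 3 libraries that held another line's genes, 1 in the shallow libraries alone, 5 with DESeq2 and 18 with the replicate block.

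Interferon-stimulated genes fell with OTX015 in 26 of 34 cases and rose in 0 (27 and 1 adjusted over the list alone, median -1.68, or -1.62 with genes of an empty group at their bound, adjusted p = 5.74e-30), with OAS2 at -2.54 ± 0.33. Of 17 histone genes 10 rose and 0 fell (13 and 0 adjusted over the list alone, median 1.61, adjusted p = 1.06e-11), with H2AC6 at 2.70 ± 0.49. MYC target genes fell in 13 of 58 cases and rose in 0 (17 and 0 adjusted over the list alone, median -0.41, adjusted p = 6.45e-11), with the ribosome assembly gene MRTO4 at -0.74 ± 0.15, which was not called in the deep libraries alone (0.13). B cell transcription factor genes fell in 11 of 28 cases and rose in 0 (18 and 0 adjusted over the list alone, median -0.60, adjusted p = 4.73e-07), with PAX5 at -0.87 ± 0.12 and IKZF1 at -1.10 ± 0.23, which the deep libraries alone did not call (0.185 and 0.0972). Of the BET inhibition markers 8 of 17 rose and 5 fell (10 and 5 adjusted over the list alone, median 1.17, adjusted p = 0.000691). Of the BET, CBP/p300 and elongation factor genes 7 of 28 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.14, adjusted p = 0.000503). Of the autophagy and lysosome genes 8 of 33 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.19, adjusted p = 0.00155). Plasma cell genes fell in 5 of 15 cases and rose in 0, also adjusted over the list alone (median -0.67, or -0.63 at the bound, adjusted p = 0.000772).

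Calls lost with an estimated correlation were those of the B cell receptor pathway genes (6 of 30 fell, 9 adjusted over the list alone, median -0.39, or -0.41 at the bound, adjusted p = 6.53e-05 and 0.0861 with an estimated correlation), where MS4A1 fell by 1.51 ± 0.25. They also include those of the activated B cell-like genes (8 of 20 fell, 11 adjusted over the list alone, median -0.67, adjusted p = 4.25e-06 and 0.17 with an estimated correlation). The same held for the NF-kB target genes (8 of 35 fell and 1 rose, 10 and 1 adjusted over the list alone, median -0.50, adjusted p = 0.00027 and 0.46 with an estimated correlation), where CXCL10 fell by 3.91 ± 0.65. It held for the MHC class II genes (2 of 16 fell, 4 adjusted over the list alone, median -0.49, or -0.44 at the bound, adjusted p = 0.00105 and 0.0649 with an estimated correlation). Toledo DMSO replicate 2, with OCILy10 genes at 70.4%, is on the DMSO side here too. The 15 other lists were not called (adjusted p = 0.0914 to 0.989). Their median, mean and test differed in sign for the glycolysis list (median -0.02, mean 0.06), the p53 targets (median -0.03, mean 0.04) and the T cell markers (median -1.44, upward test). Of 50 drawn splits 6 called 12 or more lists, the real one included.

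Within single lines OTX015 changed fewer genes. In DOHH2, ZSWIM6 rose by 2.19 ± 0.29 (adjusted p = 0.00023), ZFP36 by 1.83 ± 0.38 (0.0402) and CBLB, a ubiquitin ligase gene, by 1.31 ± 0.26 (0.0353), while CIITA fell by 2.31 ± 0.48 (0.0402), LAT2 by 1.41 ± 0.25 (0.013) and BCAT1, an enzyme of branched amino acids, by 1.39 ± 0.28 (0.0356). These were among 16 called genes, 9 higher and 7 lower (8 and 6 at least 2-fold), with 990 at an unadjusted p under 0.05. A fit of the DOHH2 libraries alone called 0. All 16 had groups apart, as had 13.5% of all genes, where exchangeable libraries would give 10%. Upper quartile scaling called 30 genes, 66.7% of them higher, and DESeq2 size factors 15, 46.7% of them higher, against 56.2% with TMM. The block called 137 genes, HEXIM1 (1.71 ± 0.47, adjusted p = 0.143 and 0.0164 with the block) and BRD2 (0.75 ± 0.16, 0.0538 and 0.0261) among them, the shallow libraries alone 2 and the deep ones 0. The count was 1, 3, 1 and 1 without DMSO replicate 2, DMSO replicate 3, OTX015 replicate 2 and OTX015 replicate 3, and 40 without OTX015 replicate 1. ZFP36 was lost without any but OTX015 replicate 1 (0.11 to 0.295), CIITA and BCAT1 without any but DMSO replicate 1 (0.0537 to 0.267), and CBLB and LAT2 without DMSO replicate 2 or 3 or OTX015 replicate 2 or 3 (0.0703 to 0.261).

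In OCILy10, OTX015 raised ALKBH5 (2.62 ± 0.31, adjusted p = 2.3e-05), PPP1R13B (2.21 ± 0.42, 0.0204) and the mitochondrial ADP/ATP carrier gene SLC25A4 (1.19 ± 0.22, 0.0173). LAT2 fell by 1.63 ± 0.25 (0.00258), the ganglioside enzyme gene ST3GAL5 by 1.63 ± 0.29 (0.0132) and PAX5 by 1.45 ± 0.23 (0.00407). In all 9 genes were called, 5 higher and 4 lower (4 and 4 at least 2-fold), each with groups apart, as had 12.6% of all genes, where exchangeable libraries would give 10%. At an unadjusted p under 0.05 there were 970, and the shallow libraries alone called 1, the deep ones 0 and a fit of the OCILy10 libraries alone 1. Library totals called 16 genes, 68.8% higher, and DESeq2 size factors 7, 42.9% higher, against 55.6% with TMM. The count was 3, 4, 5 and 4 without DMSO replicate 1, DMSO replicate 3, OTX015 replicate 1 and OTX015 replicate 3. PPP1R13B was lost without any but OTX015 replicate 2 (0.0567 to 0.174), SLC25A4 without any but OTX015 replicate 1 (0.0677 to 0.155) and ST3GAL5 without DMSO replicate 1 or 2 or OTX015 replicate 1 or 3 (0.0556 to 0.132). HEXIM1 (1.67 ± 0.47, adjusted p = 0.185) and MYC (-0.46 ± 0.44, 0.915) did not pass.

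In TMD8, OTX015 lowered interferon-stimulated genes (8 of 34 fell, median -3.01, adjusted p = 3.3e-63 and 0.00058 with an estimated correlation), among them XAF1, a death-promoting gene (-4.38 ± 0.93, adjusted p = 0.0264), and OAS2 (-3.78 ± 0.69, 0.00794), and APOL6 fell by 3.93 ± 0.62 (0.00169). MYC fell by 2.41 ± 0.46 (0.0122), and DHRS2 (3.85 ± 0.86, 0.0379), SESN3, a stress response gene (2.64 ± 0.59, 0.0351), and ZSWIM6 (1.80 ± 0.27, 0.00169) rose. Of 50 called genes 11 were higher and 39 lower (8 and 38 at least 2-fold), with 897 at an unadjusted p under 0.05, and a fit of the TMD8 libraries alone called 24. Groups were apart for 49 of the 50 and for 12.9% of all genes, where exchangeable libraries would give 10%. The block called 230, HEXIM1 among them (1.91 ± 0.47, adjusted p = 0.064 and 0.0035 with the block), the shallow libraries alone 5 and the deep ones 0. The count was 22, 33 and 11 without DMSO replicates 1, 2 and 3, and 23, 5 and 12 without OTX015 replicates 1, 2 and 3. MYC was lost without DMSO replicate 3 or OTX015 replicate 2 or 3 (0.127, 0.147, 0.0947), and DHRS2 without any library (0.0508 to 0.209). SESN3 was lost without any but OTX015 replicate 1 (0.0632 to 0.256), and XAF1 without any but DMSO replicate 2 (0.055 to 0.195). OAS2 was lost without OTX015 replicate 2 or 3 (0.0922, 0.0622).

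In Toledo, OTX015 raised H2BC5 (3.20 ± 0.80, adjusted p = 0.0296), DACT3, a Wnt pathway gene (2.83 ± 0.75, 0.0337), CCDC168 (2.70 ± 0.64, 0.0213) and HEXIM1 (2.12 ± 0.48, 0.0169). The lowest were SIRPA, which encodes a receptor of CD47 (0 counts against 122, at least 43.7-fold lower, 0.0173), MYOCD (1 count against 427, ratio 0.00218, 95% interval 5.5e-05 to 0.0122, adjusted p = 0.013) and the transcription factor gene SOX5 (1 count against 109, ratio 0.00854, 95% interval 0.000214 to 0.0486, adjusted p = 0.0125). Their DMSO counts again lay in replicate 2, the library with OCILy10 genes, at 31.4 CPM for SIRPA and 28.1 CPM for SOX5. Without it the adjusted p was 0.539 for SIRPA, 0.685 for MYOCD, 0.447 for SOX5, 0.286 for H2BC5, 0.408 for DACT3, 0.307 for CCDC168 and 0.183 for HEXIM1. Of 396 called genes 64 were higher and 332 lower (34 and 324 at least 2-fold), with 1757 at an unadjusted p under 0.05. A fit of the Toledo libraries alone called 0 genes (adjusted p = 0.619 for HEXIM1), and limma-voom called 20 higher and 16 lower. Groups were apart for 190 of them and for 10.4% of all genes, where exchangeable libraries would give 10%. The count was 2 without DMSO replicate 2, 833 and 623 without DMSO replicates 1 and 3, and 112, 9 and 5 without OTX015 replicates 1, 2 and 3. It was 8 without the 3 libraries that held another line's genes. The shallow libraries alone called 365 genes and the deep ones 0. Leaving out OTX015 replicate 2 or 3 also ended the calls named here (0.0864 to 0.196). So did OTX015 replicate 1 for SIRPA (0.0973), MYOCD (0.072), SOX5 (0.0522) and H2BC5 (0.0631), DMSO replicate 1 for H2BC5 (0.063) and DMSO replicate 3 for DACT3 (0.0591).

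For a difference between lines in the response to OTX015, edgeR called 0 genes, with 478 at an unadjusted p under 0.05. The lowest p belonged to ALKBH5 and PAX5 (adjusted p = 0.231), the phosphodiesterase gene PDE3B (0.238), NAP1L5 (0.396) and RNF227 (0.956), which all failed the test in this fit. Some genes were called with the replicate block, and with the depth term with or without the libraries that held another line's genes. Their counts stand in the section on processing.

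How far the responses to the 2 compounds overlapped was asked next. With each compound 664 genes were called higher and 720 lower, LAT2, ZSWIM6 and HEXIM1 among them, and 0 in opposite directions. Independent calls would share 65.8 and 87.1, and 12 simulations of unchanged groups against the same DMSO libraries shared 0 and 0. With no effect simulated, hardly any calls could arise to be shared, so these counts of 0 are no baseline for 664 and 720. The mean changes correlated across genes at r = 0.856, where the simulations gave 0.287, and 85.0% of genes had the same sign against 52.9%. The simulated groups were centred on the mean of the observed DMSO libraries, Toledo DMSO replicate 2 with its OCILy10 genes included. A deviation of the DMSO libraries that enters the changes of both compounds could thus not arise in the simulations. In Toledo r was 0.905, against 0.0892 simulated. The simulated groups varied independently, while NEO2734 and OTX015 libraries of the same number shared deviations (r = 0.39 to 0.90 in DOHH2 and 0.66 to 0.90 in TMD8), so the simulated values leave this out and are too low as a baseline. NEO2734 in 1 line against OTX015 in another, which share no library, correlated at -0.0479 to 0.490 (median 0.374) over 12 pairs of lines. NEO2734 in 1 line against NEO2734 in another gave 0.0239 to 0.485 (median 0.358) over 6 pairs. Both lowest values belonged to DOHH2 with Toledo. OCILy10 genes lay on the NEO2734 side in DOHH2 (replicate 3) and on the DMSO side in Toledo (replicate 2), and their part in these values was not tested. Of the 27 genes called in all 4 lines with NEO2734 and the 2 with OTX015, HYCC1 and LAT2 were in both.

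Whether NEO2734 acted differently from OTX015 was tested on the mean of the 4 lines, at doses that may differ. PAX5 was lower with NEO2734 (log2 -0.67 ± 0.12, adjusted p = 0.0187), and so were ANKLE1, BEND3 and SASH3 (-0.83, -0.88 and -0.78), which completed the 4 genes called and are named after their values were seen. For HEXIM1 the difference was 0.25 (95% interval -0.22 to 0.71), for MYC -0.61 (-1.06 to -0.15, adjusted p = 0.996) and for BRD2 0.00 (-0.17 to 0.17). For LAT2 it was -0.39 (-0.65 to -0.13), for ZSWIM6 0.43 (0.16 to 0.69), for DHRS2 0.52 (-0.25 to 1.28) and for APOL6 -0.16 (-0.74 to 0.42), and none of these passed. At an unadjusted p under 0.05 there were 499 genes, and the shallow and the deep libraries alone called 0. The count was 0 with library totals, with no filter and without the 3 libraries that held another line's genes, so that PAX5 and the other 3 genes were not called there. It was 16 with the depth term, 75 with the depth term and without the 3 libraries, and 14 with DESeq2. Changes within the deep and the shallow libraries correlated at r = 0.123, with the same sign for 54.5%. Without DOHH2 NEO2734 replicate 1 the count was 9, without OCILy10 NEO2734 replicate 2 it was 1, and it was 0 without any 1 of DOHH2 NEO2734 2, DOHH2 OTX015 3, OCILy10 NEO2734 1, OCILy10 NEO2734 3, Toledo NEO2734 1, Toledo NEO2734 2 or Toledo OTX015 1.

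Within lines, edgeR called 0 genes between NEO2734 and OTX015 in DOHH2, OCILy10, TMD8 and Toledo, with 288, 87, 113 and 99 genes at an unadjusted p under 0.05. DESeq2 called 19, 1, 1 and 0, and limma-voom 0. Without DOHH2 NEO2734 replicate 1 there were 17 in DOHH2. Groups were apart for 4.66, 4.38, 4.10 and 4.03% of genes, where exchangeable libraries would give 10%. A difference between lines was called for 0 genes by edgeR, with 74 at an unadjusted p under 0.05, and the lowest p (MLLT3, MAP3K21, NIBAN3, SLC25A24 and SKAP1) had an adjusted p of 1.

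As groups, B cell transcription factor genes were lower with NEO2734 than with OTX015 (median -0.27, adjusted p = 4.42e-12, PAX5 alone called and 5 of 28 adjusted over the list alone), as were MYC target genes (median -0.19, adjusted p = 2.44e-12, 0 of 58 called). Both held with an estimated correlation (0.00432 and 0.0488). Calls lost with it were those of B cell receptor pathway genes (median -0.18, adjusted p = 8.14e-06 and 0.126 with an estimated correlation), activated B cell-like genes (-0.09, 0.00566 and 0.585) and interferon-stimulated genes (-0.14, 0.0491 and 0.739), which were lower. So were the calls of histone genes (0.40, 6.79e-05 and 0.267), ribosomal protein genes (0.14, 0.000797 and 0.739) and autophagy and lysosome genes (0.07, 0.0338 and 0.126), which were higher with NEO2734. Of 50 drawn splits 11 called 8 or more lists, the real one included.

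CB103 was tested in OCILy10, where the question was whether an inhibitor of the Notch transcription complex changed Notch genes and others within 6 h. The Notch receptor gene NOTCH1 was at 0.05 ± 0.87, NOTCH2 at 0.07 ± 0.57, and the DNA-binding partner RBPJ at 0.03 ± 0.20. The Notch target DTX1 was at 213 ± 28.9 against 193 ± 34.1 CPM (0.14 ± 0.34), NRARP at -0.72 ± 1.14 and HES1, with 0.897 against 1.25 CPM, at -0.31 ± 0.85, and all 6 genes had an adjusted p of 1. None of the 19 Notch pathway genes passed, also adjusted over the list alone (median -0.11, adjusted p = 0.953). MYC (-0.20 ± 0.44) and HEXIM1 (0.46 ± 0.46) had an adjusted p of 1 too. HES4 was not among the genes tested.

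With CB103 edgeR called 0 genes, with 273 at an unadjusted p under 0.05. DESeq2 called 27 and limma-voom 0, and groups were apart for 2.42% of genes, where exchangeable libraries would give 10%. The lowest p, with an adjusted p of 0.372 and thus not passing, belonged to ELAPOR1 (5.91 ± 1.23), the antibody gene IGLV3-21 (134 counts against 1, ratio 160, 95% interval 28.3 to 6380), HMGN5 (4.48), GAS7 (3.93 ± 0.93) and SMARCA2 (59 counts against 2, ratio 35.3, 95% interval 9.35 to 298). Replicate 2, the library with Toledo genes at 27.1%, carried them, with ELAPOR1 at 78.0 CPM and IGLV3-21 at 50.6 CPM against at most 0.921 CPM in the other CB103 libraries, and in Toledo DMSO ELAPOR1 stood at 214 ± 172 CPM. Without CB103 replicate 1 the count was 92 and these 5 genes passed (adjusted p = 0.00197 to 0.0091). The shallow and the deep libraries alone, with 3 libraries of these groups in each set, called 0 each, and changes within them correlated at r = -0.0977.

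Cholesterol synthesis genes were lower as a group with CB103 (median -0.41, mean -0.18, adjusted p = 4.03e-12 and 0.0414 with an estimated correlation, 0.953 with fry), with 0 of 23 called and the rate-controlling SQLE at -0.65 ± 0.22 (adjusted p = 0.758). The ribosomal protein (median -0.30, adjusted p = 6.22e-06), NF-kB target (-0.22, 0.00296) and interferon-stimulated genes (-0.26, 0.00653) were lower and the ER stress genes higher (0.25, 0.00371) by the preset correlation, and their calls were lost with an adjusted p = 0.755, 0.755, 0.755 and 0.375 with an estimated correlation. Of 16 MHC class II genes 4 rose adjusted over the list alone (median 0.22, adjusted p = 0.0836), in a group whose replicate 2 held Toledo genes.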

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

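Tests and alternatives chosen only after a result was seen are those that leave out libraries with another line's genes (among them the count of lower genes in Toledo without DMSO replicate 2), the sign within the deep libraries of genes called within the shallow ones, the depth term, the deep or the shallow libraries alone and the second table's column. The response of PAX5 and ALKBH5 to NEO2734 differed between the lines, both with an adjusted p of 0.0395. PAX5 changed by log2 -1.48, -2.07, -2.35 and -0.28 and ALKBH5 by 0.31, 2.77, 1.34 and 0.53 in DOHH2, OCILy10, TMD8 and Toledo. Of 50 drawn splits within lines 9 gave 2 or more such genes, the real one included, so chance is not excluded. The highest other split gave 148, which points to a structure of the samples. With the depth term PAX5 had an adjusted p of 0.0049 and ALKBH5 of 2.7e-05, and with the depth term and without the 3 libraries 0.00095 and 3.3e-06. Without the 3 libraries alone both had 0.16, with library totals 0.13 and 0.074, and with the second table's column 0.19 and 1. A biological difference between the lines, which the design names, stays among open explanations, as untested.

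The column of OCILy10 CB103 replicate 1 in the second table had another count for 14746 genes, with a total of 5474462 against 11430777. In it MYC stood at 29.4 against 138 CPM, HEXIM1 at 5.66 against 43.5, CDKN1A at 273 against 50.5 and the histone gene H2BC21 at 89.0 against 4.29. Its correlation with the other OCILy10 libraries was 0.817 to 0.930, against 0.883 to 0.991 for the first table's column. Mitochondrially encoded genes took 14.9% of its counts against 8.47%. Which library this column holds is not known, and this limits every value obtained with it, those of PAX5 and ALKBH5 above included.

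With edgeR Toledo had more genes lower than the other lines, 538 with NEO2734 and 332 with OTX015, such as MYOCD, GBP1 and CHL1. This did not hold with limma-voom (137 lower with NEO2734 against 225, 240 and 274 in DOHH2, OCILy10 and TMD8, and 16 with OTX015 against 2, 58 and 64), nor for NEO2734 with the replicate block (456 against 515, 328 and 499). OCILy10 material in DMSO replicate 2 may explain the edgeR counts. Without that library 50 genes were lower with NEO2734, against 189 as the highest of the other lines, which kept all their libraries. A left-out library can lower a count by itself. All genes called in Toledo numbered 701, and 171, 168 and 405 without NEO2734 replicates 1, 2 and 3. They numbered 1136 and 875 without DMSO replicates 1 and 3. The comparison of 50 with 189 therefore does not settle the explanation alone. Of the lower genes 81.0% had a DMSO level at least 2 times higher in OCILy10, against 23.4% of all genes.

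Changes with NEO2734 were larger than those with OTX015, by a median log2 of 0.17 over 2730 genes, of which 86.0% lay above 0. Genes are not independent replicates, and no drawn split tested this median. The median was 0.17 within the deep and 0.18 within the shallow libraries. The genes were picked in the fit of all libraries, so these medians do not settle the part of depth. Across 12266 genes the differences between the compounds within the deep and the shallow libraries correlated at r = 0.123. They had the same sign for 54.5%. Selection of genes called with NEO2734 could not account for the larger changes alone, since the median was 0.11 over the 1484 genes called with OTX015. The dose, which the labels do not give, and the CBP/p300 bromodomains that NEO2734 also binds stay open, as untested.

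The mean response to NEO2734, with HEXIM1 higher and MYC lower, was not explained by the depth batch, since 98.5% of 1784 genes called within the shallow libraries alone had the same sign within the deep ones. The 3 libraries with another line's genes did not explain it as a whole, since 2141 genes were called without them. Of the 2630 genes 76.2% had the same sign and a call without them and 95.2% with the depth term in addition, and for the genes that lost their call the part of these libraries stays open. Chance is an unlikely cause, since 1 of 50 splits, the real one, gave 2630 genes, and the highest other gave 223. The other splits hold treated and DMSO libraries on both sides, which can lower their calls. That the response is biological is a hypothesis that these tests leave standing.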

How the results depend on the processing

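Settings with a depth term, without the 3 libraries that held another line's genes, with the shallow or deep libraries alone or with the second table's column were chosen after the data were seen. No named gene or list turned its direction in any setting in which it was called. The 20 genes named for the averaged NEO2734 contrast and MYC kept their direction and call under every setting and without any 1 of its 24 libraries. The averaged counts stayed within 1.5 times of 2630 (2366 to 2692) and 1484 (1176 to 1599) without any single library. Where a count below moved by more, the cause was not tested, with 2 exceptions. The depth sets and the fits of 1 line hold fewer libraries. For genes lower with NEO2734 in Toledo, OCILy10 material in DMSO replicate 2 was tested above.

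Lines are in the order DOHH2, OCILy10, TMD8 and Toledo, and "same-direction" counts are of genes called in all 4 lines with NEO2734, OTX015 and both. DESeq2's Wald test gave 671, 359 and 434 genes in the first 3 lines with NEO2734, 86, 81, 127 and 628 with OTX015, 19, 1 and 1 in the first 3 lines and 14 on average between the compounds, 27 with CB103, and same-direction counts of 68, 5 and 4. Limma-voom gave 446 in OCILy10 and 307 in Toledo with NEO2734, 7, 95, 82 and 36 with OTX015, 2 between the compounds on average, and 45 same-direction genes with NEO2734. The replicate block, whose numbers did not pair in Toledo, gave 951, 648 and 751 in the first 3 lines and 27 differing between lines with NEO2734, 137, 229 and 230 in the first 3 lines, 2421 on average and 3 differing between lines with OTX015, 8 between the compounds on average, 14 with CB103, and same-direction counts of 114, 18 and 17.

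Without the 3 libraries NEO2734 gave 197 in DOHH2, 214 in OCILy10 and 82 in Toledo, with 0 differing between lines, OTX015 gave 37, 30, 85 and 8, the compounds differed on average in 0, and same-direction counts were 16, 1 and 1. The depth term gave 1438, 994, 1058 and 1687 with NEO2734, 4242 on average and 32 differing, 260, 302, 340 and 1048 with OTX015, 2935 on average and 1 differing, 16 between the compounds on average, and 191, 27 and 26 same-direction genes. Both together gave 1706, 1970 and 1848 in the first 3 lines, 4415 on average and 153 differing with NEO2734, 678, 937, 746 and 259, 3288 on average and 28 differing with OTX015, 2 in TMD8 and 75 on average between the compounds, and 233, 54 and 51 same-direction genes. With DESeq2 size factors in addition these were 1708, 2007, 1867, 4428 and 142, then 674, 943, 780, 3306 and 30 (without Toledo), 2 and 78, and 239, 60 and 55. With library totals in addition they were 1836, 2060, 2013, 4549 and 142, then 793, 985, 786, 3391 and 38 (without Toledo), 2 and 74, and 256, 60 and 54.

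The shallow libraries gave 193, 2 and 92 in the first 3 lines and 0 differing with NEO2734, 2, 1 and 5 in the first 3 lines and 951 on average with OTX015, 0 between the compounds on average, and 1, 1 and 1 same-direction genes. The deep libraries gave 0 in DOHH2, TMD8 and Toledo, 727 on average and 0 differing with NEO2734, 0 in each line and 62 on average with OTX015, 0 between the compounds on average, and 0, 0 and 0 same-direction genes. A fit of 1 line alone gave 68 in DOHH2 and 0 in Toledo with NEO2734, and 0, 1, 24 and 0 with OTX015. The second table's column, of which it is not known which library it holds, gave 63 in OCILy10 and 0 differing with NEO2734, 4 in OCILy10 with OTX015, 0 between the compounds on average, 16 with CB103, and 11, 1 and 1 same-direction genes. For the difference between lines with NEO2734, DESeq2 size factors gave 1, library totals 0, upper quartile 1 and no filter 1. For the compounds on average these gave 2, 0, 2 and 0, and the stricter filter 2. With OTX015 library totals gave 28 in DOHH2 and 16 in OCILy10, upper quartile 30 and 17, and no filter 27 in TMD8. Calls of gene lists numbered 38, against 19 with an estimated correlation and 17 with it, the depth term and the 3 libraries left out. With fry, 14 list results were weaker and 5 stronger in its directional form, and 12 weaker and 14 stronger in its mixed form.

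Leaving out 1 library at a time gave, with NEO2734, 119 to 408 in DOHH2, 31 to 64 in OCILy10, 103 to 181 in TMD8 and 90 (without DMSO replicate 2) to 1136 (without DMSO replicate 1) in Toledo. With OTX015 it gave 1 to 40, 3 to 11, 5 to 33 and 2 (without DMSO replicate 2) to 833 (without DMSO replicate 1). Between the compounds it gave 0 to 17 in DOHH2 and 0 to 9 on average, and with CB103 0 to 92, each highest value without a single library, DOHH2 NEO2734 replicate 1 or OCILy10 CB103 replicate 1.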

Other observations

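Some members of the gene lists not described above also changed on the mean of the 4 lines. With NEO2734 the interleukin-2 receptor gene IL2RA fell (-3.24 ± 0.60, adjusted p = 0.000205), as did the Notch target DTX1 (-0.89 ± 0.17, 0.000361), the hexokinase gene HK2 (-0.73 ± 0.15, 0.000511), the caspase gene CASP8 (-0.81 ± 0.15, 0.000279) and the survival gene BCL2L1 (-0.86 ± 0.20, 0.00175). The p53 targets RRM2B (0.64 ± 0.14, 0.00129) and SESN2 (1.28 ± 0.24, 0.000275) rose. With OTX015 IL2RA fell (-2.70 ± 0.58, 0.00223), and TXNIP (0.87 ± 0.16, 0.000556) and SESN2 (1.00 ± 0.24, 0.00639) rose. In the deep libraries alone IL2RA (0.059), SESN2 (0.124), BCL2L1 (0.0637) and CASP8 (0.0796) did not pass with NEO2734.

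Within lines the 10 splits of 6 libraries are too few for a share under 0.05. With NEO2734 1 of 10 splits in each line, the real one, gave as many genes, with 372 in DOHH2 (highest other 26), 130 in OCILy10 (0), 278 in TMD8 (1) and 701 in Toledo (366). With OTX015 it was 1 of 10 in each line as well, with 16 (highest other 1), 9 (0), 50 (0) and 396 (347). The Toledo splits of 366 and 347 put DMSO replicates 2 and 3 with NEO2734 replicate 1, or DMSO replicates 2 and 3 with OTX015 replicate 2. The split of 26 in DOHH2 put the deep libraries NEO2734 replicate 1 and DMSO replicate 1 on a side. Where replicate numbers pair the libraries (DOHH2, TMD8 and OCILy10 with NEO2734), the 3 other splits that part every pair gave 0 genes. The splits that gave 26 and 1 genes in DOHH2 and 1 in TMD8 kept a pair together, and in OCILy10 with NEO2734 and TMD8 with OTX015 all other splits gave 0.

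Between NEO2734 and OTX015 edgeR called 0 genes in each line (288, 87, 113 and 99 at an unadjusted p under 0.05, DESeq2 19, 1, 1 and 0, limma-voom 0), so 10 of 10 splits gave as many, with 21, 1, 0 and 0 as the highest others. The 21 in DOHH2, with the 2 deep libraries on a side, point to a structure of the samples. With CB103 edgeR called 0 genes (273 at an unadjusted p under 0.05, DESeq2 27, limma-voom 0) and 10 of 10 splits gave as many. The highest other, 100, put the 3 deep libraries against the 3 shallow ones. It points to a structure of the samples. Fits within the deep and within the shallow libraries held 3 libraries of these groups each. CB103 had a single library in the deep set and DMSO a single library in the shallow set, and the spread came in part from other groups. These fits do not settle whether depth hid or made calls.

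For the averages 50 splits were drawn within lines. For OTX015, with HEXIM1 higher, 1 of 50 gave 1484 genes (highest other 1), which makes chance unlikely. For NEO2734 1 of 50 gave 27 genes called in all 4 lines with the same sign (0), for OTX015 2 (0) and for both 2 (0), with 1 of 50 each. In the split of 223 genes with NEO2734 9 of 12 libraries kept their label. Between the compounds 2 of 50 splits gave 4 or more genes, PAX5 among the real 4. The other gave 476, which points to a structure of the samples. It put 1 deep library in a group against 8 in the other, and another split with these numbers gave 0 genes, so the part of depth stays open. For a difference between lines edgeR called 0 genes with OTX015 (478 at an unadjusted p under 0.05) and 50 of 50 splits gave as many, with 133 as the highest other, which points to a structure of the samples. Between the compounds it called 0 (74 at an unadjusted p under 0.05) and 50 of 50 gave as many, with 2 as the highest other. For the number of gene lists called chance is not excluded: 8 of 50 gave 13 or more with NEO2734 (highest other 18), 6 of 50 gave 12 or more with OTX015 (14) and 11 of 50 gave 8 or more between the compounds (13).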
